A study of Carassius auratus with 6 samples.

How the data were processed

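RNA from the hepatopancreas of Crane-top red goldfish (HDH, 3 samples) and Pearl-scale goldfish (PS, 3 samples) was extracted with TRIzol and made into libraries with a NEBNext Ultra RNA kit, per the labels' protocols. The authors deposited FPKM values (fragments per kilobase of gene model, scaled to the mapped fragments of the library) in 1 table with 1 column per sample. STAR 2.5.1b, HTSeq 0.6.0 and DESeq2 are named in the submitters' processing notes, with no role or order. The genome build, the strand setting, the treatment of reads that map to several places and any filter are not given in the sources used here. Each column was tied to its sample through the description in the labels, and each sample to its breed through its title.

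The table held 80637 loci, of which 66730 carried a bare locus number as name and 4356 lay outside the reference annotation. The gene IDs of 76281 loci were found in the reference gene table of assembly ASM336829v1, and 76244 of these had the same start and end, so coordinates are given as in the deposited table and names were taken from both. The reference gave 10414 loci a symbol, transfer RNAs left out; 10931 had a name from either source. Most goldfish genes therefore entered the counts without a usable name, and list members are only those with a matching name. In 154 tested genes the 2 sources gave different symbols, and either was accepted for list membership.

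FPKM values were analysed as deposited, as log2(FPKM + 1), in the 18159 genes with a mean of at least 1 FPKM over the 6 samples; 4800 of these had a name. Fold changes are on that scale, which understates the change of low genes. The breeds were compared with limma 3.58.1 (linear model, empirical Bayes with a mean-variance trend, two-sided, PS minus HDH, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Because the values are FPKM, no count model was used. A value of 0 in such a table can be a failed estimate, so genes at 0 are described as listed at 0, with each library's value. A rank or permutation test of 3 against 3 samples cannot go below an exact p of 0.1. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

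Before the data were examined, 25 gene lists, their matching rule and the genes to be named were fixed. Named genes were the 10 with the largest log2 fold change in each direction among called genes with a name and no overlap between breeds; of each list, up to 4 called members with the largest change, or the 2 with the smallest p where none was called; and the tested copies (up to 3 each) of cyp7a1, cyp8b1, cyp27a1, hsd3b7, akr1d1, baat, nr1h4, abcb11, fasn, srebf1, ppara, cpt1a, apob and mttp, and of a further gene that is not reported here. Further list members (mvk, dhcr7, insig1, fga, fgb, zp3b, esr1, vtg3, fabp2, apoea, cdx1b, muc2.1, the unfiltered cyp7a1) were named after their values were seen. Synonyms such as cyp27a2 for cyp27a1 were added from names alone. Lists with at least 3 tested members (23 lists) were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the lists, with camera using an estimated correlation and with fry. camera tests whether a list shifts one way relative to other genes, and fry whether its genes move one way on balance. The median, mean and tests of a list differed in sign for bile acid synthesis, fatty acid synthesis, triglyceride synthesis, exocrine pancreas, vitellogenin and egg coat, heat shock and ER stress, and xenobiotic metabolism.

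The number of reads per library is unknown. Relative depth was read from loci with a mean under 0.1 FPKM. In these the commonest ratio between 2 libraries was taken to be that of 1 read against 1 read. Against HDH replicate 1, only 115 to 138 of the 3454 to 4569 loci compared lay at that ratio, so the depths are rough. By this estimate the deepest library exceeded the shallowest by a factor of 1.40. No interval that needs counts is given.

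Simulated data had the means and spreads of the 18159 genes and 200 changed genes. On these the test recovered 53 of 100 genes changed by 1 and 84 of 100 changed by 2 on the log2 scale, with 3 false calls. The changed genes were drawn from those with a mean log2(FPKM + 1) above 2, so recovery of lower genes was not tested. The noise was independent between genes, without shifts shared within a library, so the 3 false calls do not measure those in the real data. The alternatives planned at the same time as the lists were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, scaling without exocrine pancreas genes, the replicate number as a block, a robust variance model, a fold change threshold, summed copies, other set tests, and leaving out each library. A fit with exocrine pancreas content as a covariate was added after seeing the data.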

Results

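Messenger RNA was measured by RNA sequencing in the hepatopancreas, the organ in which carp-like fish hold liver and pancreatic tissue together, of 2 breeds of goldfish (Carassius auratus). The Crane-top red goldfish (HDH) and the Pearl-scale goldfish (PS) were each represented by 3 samples. The series set out to compare the breeds because they deposit lipid differently. Its title points to bile acid synthesis. The labels do not say whether the samples came from separate fish, nor their sex, age, diet or time of sampling. The p-values therefore measure the spread between these samples. Expression was given as FPKM, and the columns summed to between 738630 FPKM (PS replicate 1) and 793386 FPKM (HDH replicate 3). Between 41031 (PS replicate 2) and 44866 (PS replicate 1) of the 80637 loci lay above 0. The number of reads per library is unknown. From the ratios of the lowest values, depth relative to HDH replicate 1 was roughly estimated. It came to 1.24 and 0.901 for HDH replicates 2 and 3, and to 1.10, 0.883 and 1.09 for PS replicates 1, 2 and 3.

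The breeds differed in single genes of sterol, lipid and bile acid metabolism. In PS, 6 of 14 measured genes of cholesterol synthesis and uptake were lower, with hmgcs1, the enzyme that makes the HMG-CoA used for sterols, at 13.6 ± 3.02 FPKM against 45.6 ± 19.9 in HDH (means ± SD, n = 3 libraries per breed, here and below). As a list these genes were called lower with a preset correlation and not with an estimated correlation (limma camera, adjusted p = 0.00575 and adjusted p = 0.948). Bile acid synthesis genes went both ways, with slc27a2a and cyp7b1 higher and cyp7a1b, scp2a and scp2b lower in PS. Of these, only slc27a2a kept its call in every alternative fit. The lipid droplet coat gene plin2 was lower in all PS libraries (3.46, 6.08 and 2.76 FPKM) than in any HDH library (23.4, 145 and 27.9 FPKM). Of 15 hepatocyte markers 3 were higher in PS, among them hp (haptoglobin) and tfa (transferrin). That list was called higher in PS with a preset correlation and not with an estimated correlation (adjusted p = 0.0212 and adjusted p = 0.948). The single-gene calls of hmgcs1, plin2, hp and tfa were each lost in some alternative fits.

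The first principal component held 57.1% of the variance and separated the breeds, with HDH between -46.3 and -42.2 and PS between 32.3 and 63.9. The second, with 19.3%, parted PS replicate 1 from PS replicate 3. Across the 18159 genes tested, Pearson correlations of log2(FPKM + 1) were 0.967 to 0.977 within HDH, 0.927 to 0.958 within PS and 0.873 to 0.924 between breeds.

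**Figure D1:**
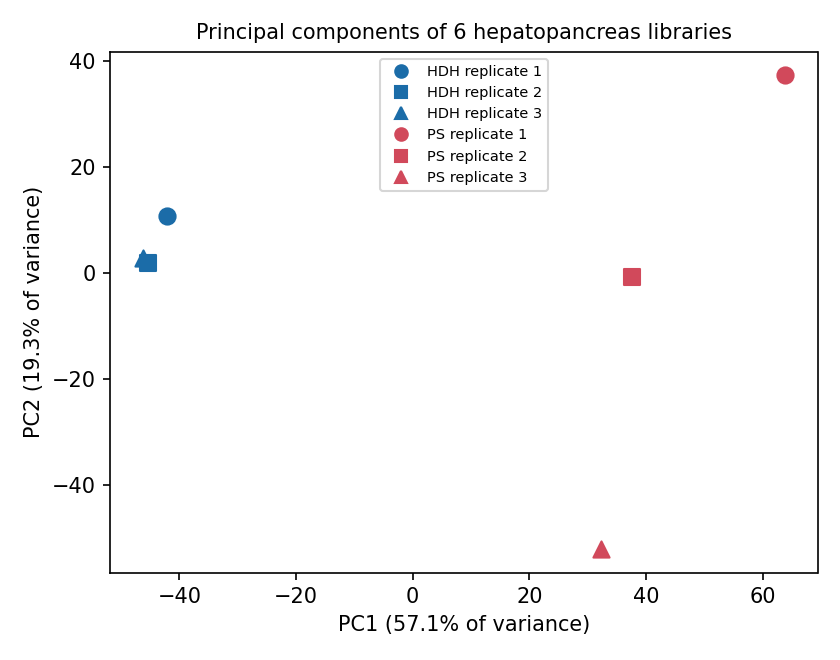
Scores of the 6 libraries on the first (x axis, 57.1% of the variance) and second (y axis, 19.3%) principal components of log2(FPKM + 1) over 18159 genes; colour gives the breed and shape the replicate number. The 3 HDH libraries sit together below -42 on the first component, and the 3 PS libraries lie above 32 and spread along the second.

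At a Benjamini-Hochberg adjusted p under 0.05 in limma, 799 genes were higher and 1437 lower in PS than in HDH, which is 12.3% of those tested. An unadjusted p under 0.05 was reached by 5436 genes. In all 2236 called genes the 3 libraries of one breed lay above the 3 of the other, as they did in 37.2% of all genes tested. For a single gene chance gives 10%. Genes can shift together within a library, so the share over genes does not test the breeds. An absolute log2 fold change of at least 1 was met by 384 of the higher and 582 of the lower genes. The higher genes were 35.7% of the calls as deposited, but 50.3% (1054 higher, 1043 lower) after median-of-ratios scaling and 46.6% (963 higher, 1104 lower) after quantile normalization. The balance of directions thus depended on the scaling. Leaving out any of HDH replicates 1, 2 or 3 or PS replicate 1 moved the higher count by over 1.5 times (to 429, 428, 307 and 495). The lower count moved as far without any library except PS replicate 3 (532 to 941).

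Among called genes with a name and no overlap between breeds, the largest increase was in slc13a5a, a citrate transporter gene (gene ID 113038376, chromosome 21, 8716842 to 8789315). It stood at 11.2 ± 0.847 FPKM in PS and 0.576 ± 0.394 in HDH, a log2 fold change of 2.98 ± 0.18 (SE) on the log2(FPKM + 1) scale with an adjusted p of 0.000592. Its neighbour serpinf2a, the alpha-2-antiplasmin gene (chromosome 21, 8709007 to 8712689), rose by 1.82 ± 0.30 (SE, adjusted p = 0.0141). The others of the 10 largest named increases were acp5a (log2 fold change 2.85), tdg (2.39), siva1 (2.16), slc27a2a (2.06), eef2k (2.06), onecutl (2.02), afp4 (2.01) and ankrd37 (1.79). The calls of serpinf2a, siva1 and afp4 were lost without HDH replicate 2, that of serpinf2a also without HDH replicate 3, that of siva1 without HDH replicate 1, and that of afp4 without any 1 library except PS replicate 1.

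By the same rule, the largest named decrease was in a copy of rpl35, a ribosomal protein gene (gene ID 113038961, chromosome 21, 22350432 to 22352959). It stood at 377 ± 171 FPKM in HDH and 9.69 ± 3.02 in PS, a log2 fold change of -5.08 ± 0.36 (SE, adjusted p = 0.00102). The mitochondrial uncoupling protein gene ucp3 read 22.6, 26.7 and 30.6 FPKM in HDH and 0.802, 1.55 and 0 FPKM in PS (adjusted p = 0.00168). For cyp27b1, the vitamin D 1-alpha-hydroxylase gene, the log2 fold change was -3.88 ± 0.45 (SE, adjusted p = 0.00502). prr35 was listed at 0 in all 3 PS libraries and at 17.0, 10.9 and 12.4 FPKM in HDH. The rest of the 10 were rbfox1l (-3.45), plin2 (-3.25), nfil3-6 (-2.93), si:dkey-22f5.9 (-2.80), prelid3b (-2.79) and gadd45aa (-2.60). Without HDH replicate 3 the calls of rbfox1l, plin2, nfil3-6, si:dkey-22f5.9 and prelid3b were lost. Those of plin2 and prelid3b were also lost without any 1 PS library, and that of prelid3b without HDH replicate 2. Goldfish carry close copies of many genes, and reads of such copies can be split or discarded, so a difference in a single copy is uncertain.

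Of the 55 named genes past the threshold, 16 stayed past it in every alternative in which they were tested: slc13a5a, acp5a, tdg, slc27a2a, eef2k, onecutl, ankrd37, rpl35, ucp3, cyp27b1, prr35, gadd45aa, fdps, mogat3a, esr2b and pdia4. Of these tdg, onecutl, ankrd37 and fdps were not tested in the fit with a mean of at least 5 FPKM. Median-of-ratios scaling ended the calls of 12, which were cyp7a1b, scp2a, msmo1, lss, elovl2, acaa1, lipca, ghrb, vtg8, calr, psma2a and ugt5d1. The replicate block ended 20 of the 55 calls. These were cyp7b1, cyp7a1b, scp2a, scp2b, slc51a, lss, elovl2, acaa1, cetp, pfkla, itih3b.1, krt18b, vtg8, nr1d2a, per3, herpud1, calr, psma2a, ugt5d1 and nr1i2. With no filter on low values 24 of the 55 calls ended, and leaving out 1 library ended between 18 (PS replicate 2 or PS replicate 3) and 37 (HDH replicate 3). None of the 55 changed sign when 1 library was left out. The fold of plin2 moved by over 1.5 times without HDH replicate 2 (log2 fold change -2.43) and that of rbfox1l without PS replicate 2 (-2.84).

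Bile acid synthesis, the process in the title of the series, was measured through 7 genes, of which 2 were higher, 3 lower and 2 not past the threshold. Adjusted over the list alone, 2 were higher and 4 lower. slc27a2a, which codes for an acyl-CoA synthetase of very long-chain fatty acids and bile acid precursors (gene ID 113118058; chromosome 18, 538492 to 544954), stood at 51.3 ± 5.09 FPKM in PS and 11.5 ± 1.23 in HDH, with a log2 fold change of 2.06 ± 0.14 (SE, adjusted p = 0.000787). cyp7b1, the oxysterol 7-alpha-hydroxylase of the alternative pathway (chromosome 27, 2388194 to 2395477), rose from 11.5 ± 1.13 to 24.2 ± 4.48 FPKM (log2 fold change 1.00 ± 0.17 SE, adjusted p = 0.0159). cyp7a1b, a copy of the cholesterol 7-alpha-hydroxylase that opens the classic pathway (chromosome 7, 25081518 to 25098103), fell from 4.82 ± 0.261 to 2.97 ± 0.515 FPKM (log2 fold change -0.56 ± 0.12 SE, adjusted p = 0.0346). The copies scp2a and scp2b of sterol carrier protein 2 fell by 0.68 and 0.60 on the log2 scale. cyp27a2, a sterol 27-hydroxylase gene, stood at 32.8 ± 2.58 FPKM in HDH and 34.6 ± 3.16 in PS (log2 fold change 0.08 ± 0.13 SE, adjusted p = 0.735). The copy named cyp7a1 lay under the filter, at 1.29, 0.284 and 0.127 FPKM in HDH and 0.0642, 0.0804 and 0.0965 in PS. As a set the 7 genes had no common direction relative to other genes (camera adjusted p = 0.953). In the test of fry for a change in either direction the list passed (adjusted p = 0.000119), as did 17 of 23 lists. The calls of cyp7a1b and scp2a ended under median-of-ratios scaling and in 5 and 6 of the 6 fits that left out 1 library, and that of cyp7b1 without HDH replicate 1 or 3. That of scp2b ended without HDH replicate 3, and those of all 4 with the replicate block. cyp8b1, hsd3b7, akr1d1 and baat had no gene matched by name and were not analysed here.

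Of 8 genes of bile acid transport and signalling, 2 were lower and none higher in PS. Adjusted over the list alone, 1 was higher and 2 lower. slc51a, a subunit of the organic solute transporter that moves bile acids across the basolateral membrane, fell from 25.04 ± 2.20 to 14.5 ± 0.933 FPKM (adjusted p = 0.0143). The organic anion transporter gene slco1d1 fell from 16.2 ± 0.336 to 6.61 ± 2.37 FPKM (adjusted p = 0.0185). The slco1d1 call was lost without any 1 HDH library or PS replicate 2, and that of slc51a without HDH replicate 2 or 3 and with the replicate block. The bile acid receptor gene nr1h4 read 14.4 ± 0.920 FPKM in HDH and 14.04 ± 0.965 in PS (log2 fold change -0.04 ± 0.11 SE, adjusted p = 0.862). The bile salt export pump gene abcb11b read 68.2 ± 9.23 and 57.9 ± 7.93 FPKM (adjusted p = 0.386). The list did not pass the set test (camera adjusted p = 0.953).

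Cholesterol synthesis and uptake genes were lower in PS as a list (camera adjusted p = 0.00575, median log2 fold change -0.91, 14 genes). The call was lost with an estimated correlation between the genes (p = 0.283, adjusted p = 0.948) and in fry (adjusted p = 0.147). In it 6 genes were lower, none higher and 8 not past the threshold, and 9 were lower when adjusted over the list alone. The 6 were hmgcs1, msmo1, fdps, lss, mvk and dhcr7, all enzymes between acetyl-CoA and cholesterol. hmgcs1 (gene ID 113109545; chromosome 10, 2584220 to 2592373) had a log2 fold change of -1.61 ± 0.31 (SE, adjusted p = 0.0229). For fdps, the farnesyl diphosphate synthase gene (chromosome 16, 16853011 to 16856862), the mean fell from 3.80 ± 0.990 to 0.769 ± 0.171 FPKM (adjusted p = 0.00638). msmo1 fell by 1.46 and lss by 1.21, although both calls ended under median-of-ratios scaling, and that of hmgcs1 ended without HDH replicate 3, PS replicate 1 or PS replicate 3. The calls of msmo1 and lss also ended without any 1 library except PS replicate 2, and with no filter those of all 3 ended. The exception in direction was insig1, a sterol-sensing regulator gene, at 15.9, 70.1 and 35.0 FPKM in HDH and 54.2, 64.1 and 61.5 FPKM in PS (adjusted p = 0.318). Within PS, replicate 2 held the highest values of hmgcs1, msmo1 and lss.

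**Figure D2:**
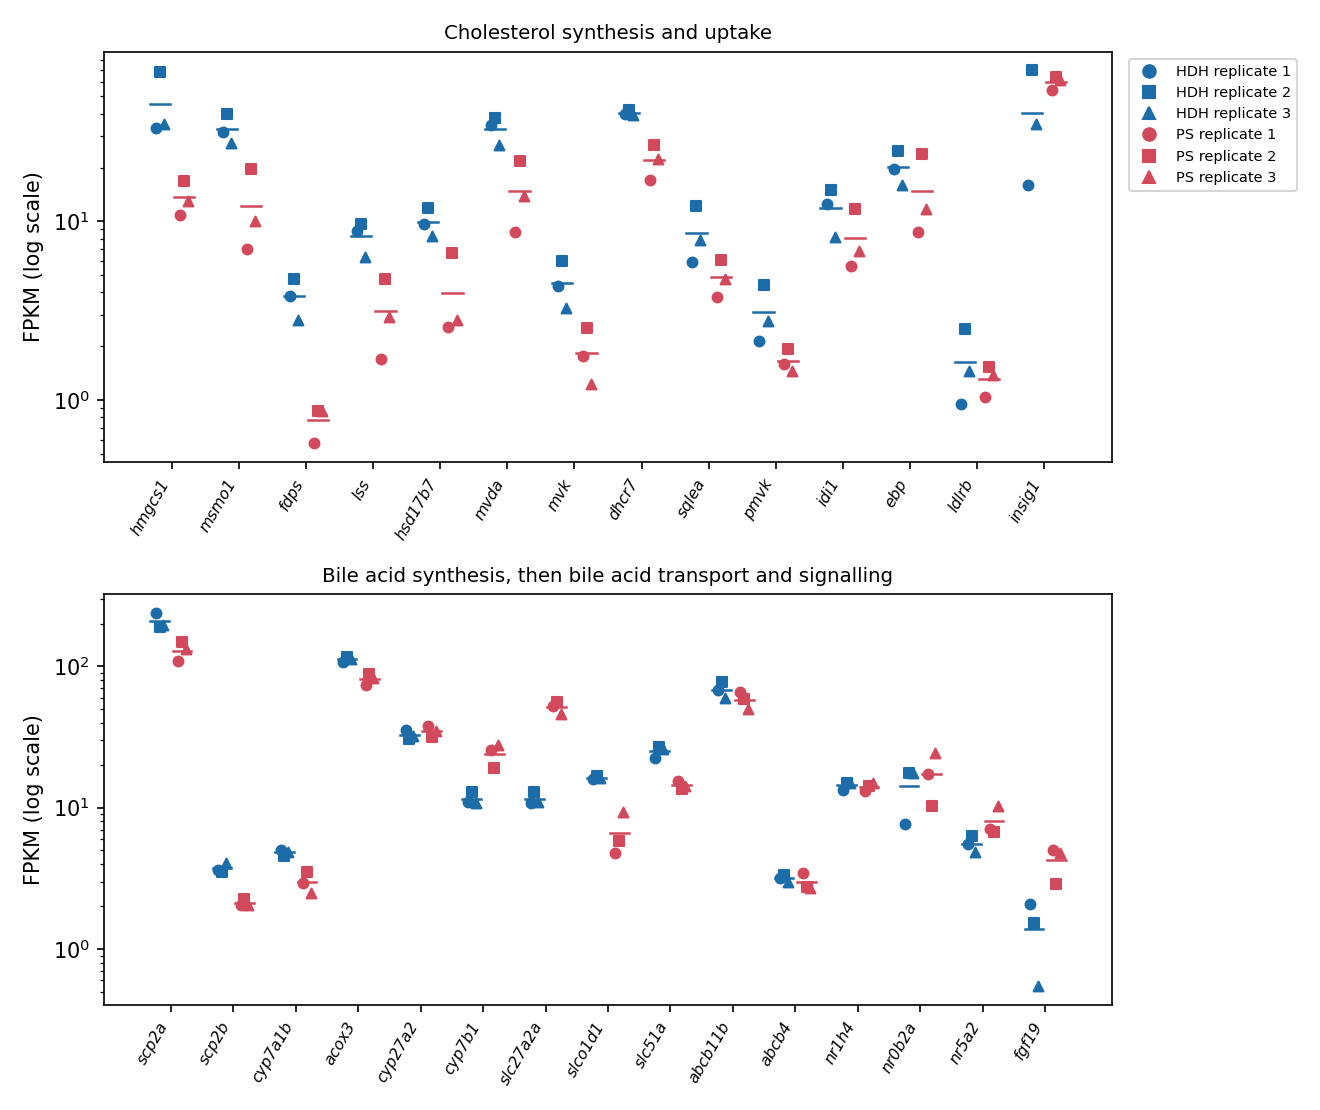
FPKM on a log axis of each library for the 14 genes of cholesterol synthesis and uptake (top) and for the 7 genes of bile acid synthesis followed by the 8 of bile acid transport and signalling (bottom), each group ordered by fold change; points are libraries and short lines breed means. hmgcs1, fdps and dhcr7 lay lower in all PS libraries than in any HDH library, and slc27a2a and cyp7b1 higher.

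Genes of fatty acid and triglyceride metabolism showed few calls. Of 9 fatty acid synthesis genes, 2 were lower and none higher in PS (adjusted over the list alone, 3 lower and 1 higher). acacb, an acetyl-CoA carboxylase gene, fell from 43.1 ± 10.2 to 20.0 ± 1.13 FPKM (adjusted p = 0.0207), a call lost without HDH replicate 2, HDH replicate 3, PS replicate 1 or PS replicate 2. elovl2, an elongase gene, fell by 1.16 on the log2 scale, a call that ended under median-of-ratios scaling and without any 1 library except PS replicate 2. srebf1 read 4.79 ± 1.42 and 5.15 ± 0.932 FPKM (adjusted p = 0.778). fasn was not analysed here. Of 11 genes of triglyceride synthesis and lipid droplets, plin2 was lower (chromosome 15, 14167503 to 14171240, log2 fold change -3.25 ± 0.68 SE, adjusted p = 0.0307). mogat3a, a monoacylglycerol acyltransferase gene, was higher, going from 15.9 ± 1.41 to 36.9 ± 5.17 FPKM (adjusted p = 0.00689). Adjusted over the list alone the counts were again 1 and 1. The plin2 call was lost with no filter on low values and without HDH replicate 3 or any 1 PS library; over all 6 fits that left out 1 library its log2 fold change lay between -3.72 and -2.43. Of 17 fatty acid oxidation genes, hadhab and acaa1 fell by 0.71 and 0.54 and none rose, with 4 lower and 1 higher when adjusted over the list alone. The acaa1 call ended under median-of-ratios scaling and without any 1 library, and that of hadhab without HDH replicate 2 or 3. cpt1aa, the entry step of mitochondrial oxidation, had a log2 fold change of 0.17 ± 0.14 (SE, adjusted p = 0.476), and pparaa of 0.43 ± 0.15 (SE, adjusted p = 0.117).

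Lipases and lipid carriers were likewise called in single genes. Of 4 lipase genes, lipca, the hepatic lipase gene, fell from 13.2 ± 0.952 to 5.28 ± 2.35 FPKM (adjusted p = 0.0429), a call that ended under median-of-ratios scaling and without any 1 HDH library or PS replicate 2. Adjusted over the list alone, 2 were lower. Of 20 genes of lipoproteins and lipid transport, cetp, the cholesteryl ester transfer protein gene, was lower, at 114 ± 0.712 FPKM in HDH and 67.1 ± 6.17 in PS (adjusted p = 0.0136), a call lost without HDH replicate 3 and with the replicate block. In this list 4 were lower when adjusted over the list alone. The 3 most abundant copies of apob, which codes for the core protein of lipoproteins, had log2 fold changes of -0.07 ± 0.18 (apobb.1), -0.58 ± 0.15 (apoba) and -1.86 ± 0.55 (apobb.2, all SE), with adjusted p of 0.834, 0.0589 and 0.0759. With the exocrine covariate apoba and apobb.2 were called lower (adjusted p = 0.0436 and 0.0442), and without PS replicate 2 so was apobb.2, at a log2 fold change of -1.20 (adjusted p = 0.0466). apoea, an apolipoprotein E gene, read 115.6 FPKM in PS replicate 1 and at most 1.43 FPKM in any other library (adjusted p = 0.298). mttp was not analysed here. Of 9 genes of glucose and glycogen metabolism, pfkla, a phosphofructokinase gene, rose by 0.75 ± 0.14 on the log2 scale (SE, adjusted p = 0.0211), a call lost with no filter, with the replicate block and without any 1 library except PS replicate 2. Of these 4 were higher and 1 lower when adjusted over the list alone. Of 13 regulators of lipid and energy use, ghrb, a growth hormone receptor gene, fell from 84.7 ± 16.8 to 25.8 ± 14.004 FPKM (adjusted p = 0.0474). The ghrb call ended under median-of-ratios scaling and without any 1 HDH library or PS replicate 2, and none passed when adjusted over the list alone. None of these 7 lists passed the set test (camera adjusted p between 0.246 and 0.953).

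**Figure D3:**
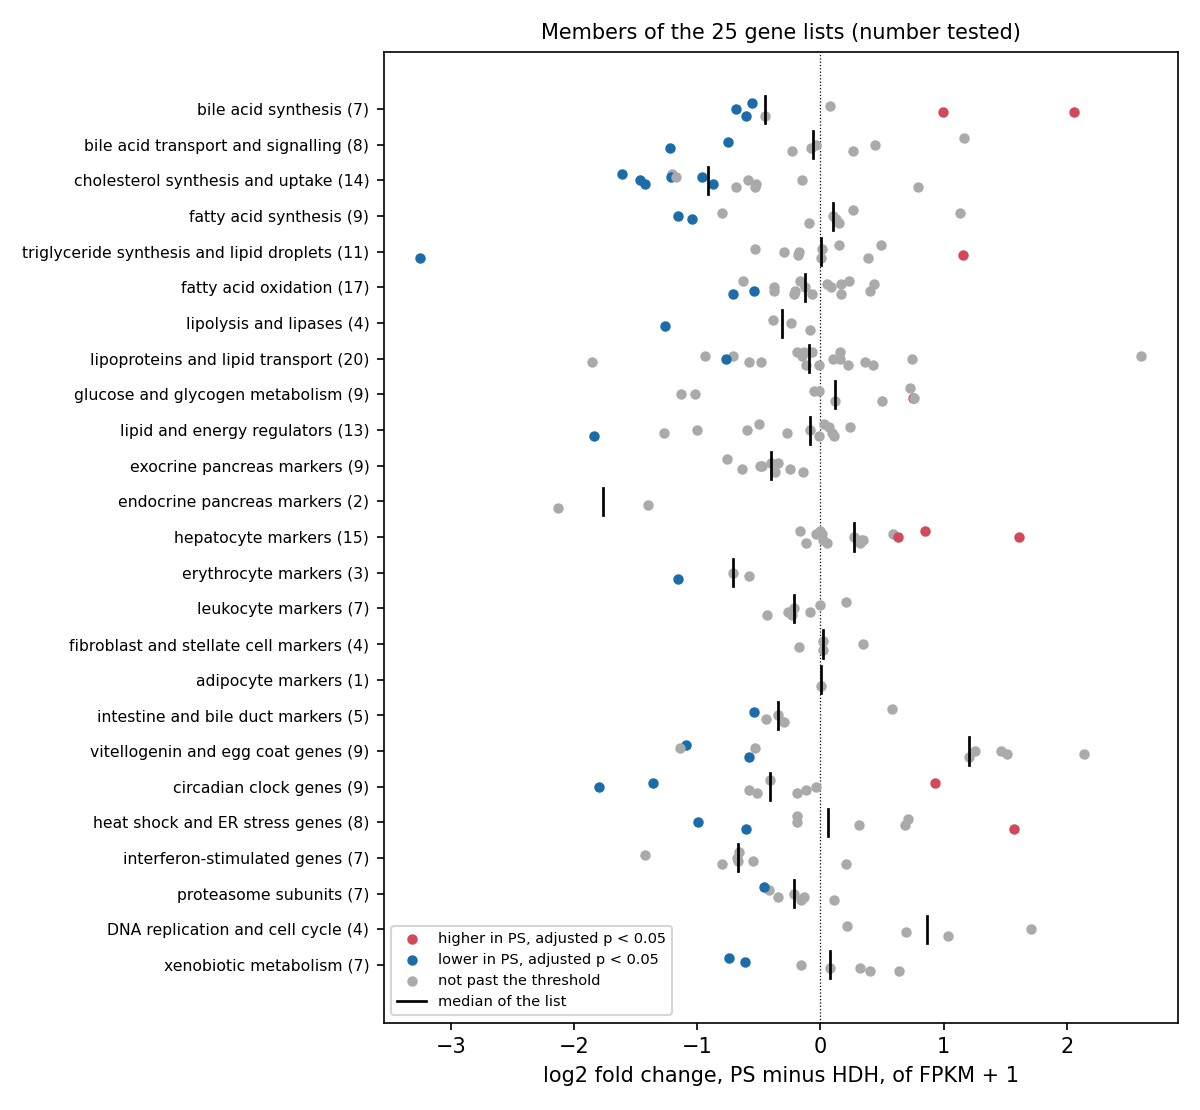
Log2 fold change (x axis, PS minus HDH, of FPKM + 1) of every tested member of the 25 gene lists, with the number tested in parentheses; red and blue points passed an adjusted p of 0.05, grey points did not, and black lines are list medians. The cholesterol list has a median of -0.91 and the hepatocyte list of 0.28.

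Hepatocyte markers were higher in PS as a list (camera adjusted p = 0.0212, median log2 fold change 0.28, 15 genes). The call was lost with an estimated correlation (p = 0.235, adjusted p = 0.948), in fry (adjusted p = 0.216), with no filter on low values, after quantile normalization and without PS replicate 3. In it 3 genes were higher, none lower and 12 not past the threshold, with the same counts when adjusted over the list alone. hp rose from 305 ± 38.1 to 1020 ± 554 FPKM (adjusted p = 0.0341). tfa rose from 4790 ± 335 to 8642 ± 1100 FPKM (adjusted p = 0.0114), and itih3b.1, an inter-alpha-trypsin inhibitor gene, from 533 ± 46.9 to 825 ± 80.5 FPKM (adjusted p = 0.0318). All 3 calls were lost with no filter and without HDH replicate 3. Those of hp and itih3b.1 were also lost without HDH replicate 1, HDH replicate 2 or PS replicate 1, and that of itih3b.1 without PS replicate 3. The fibrinogen genes fga and fgb had log2 fold changes of 0.00 ± 0.12 and 0.05 ± 0.12 (SE) and did not pass.

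Markers of other cell types that a hepatopancreas sample can hold varied by library. The 9 digestive enzyme genes of the exocrine pancreas summed to 5922, 3107 and 3374 FPKM in HDH and to 7724, 12595 and 243 FPKM in PS. PS replicate 3 thus lay below and PS replicates 1 and 2 above every HDH library. ela3l, an elastase gene, read 688, 378 and 407 FPKM in HDH and 775, 1422 and 18.95 FPKM in PS, and sycn 299.6, 139 and 174 against 281, 445 and 14.6 FPKM. None of the 9 passed, over all genes or adjusted over the list alone (camera adjusted p = 0.953). Without PS replicate 3 the list was higher in PS (camera adjusted p = 8.2e-05, p = 0.200 with an estimated correlation). Of the endocrine hormone genes, sst2 (somatostatin) read 12.02, 12.3 and 50.4 FPKM in HDH and 5.12, 3.12 and 3.21 in PS (log2 fold change -2.13, adjusted p = 0.0505). It was called lower with a pseudocount of 0.1 (adjusted p = 0.0410), with a mean of at least 5 FPKM (adjusted p = 0.0436) and without HDH replicate 3, at a log2 fold change of -1.47 (adjusted p = 0.0282). gcgb (glucagon) read 2.41, 3.96 and 14.7 against 1.58, 0.885 and 1.98 FPKM (adjusted p = 0.145). Both were lower when adjusted over the list alone. The red cell gene hemgn fell from 17.99 ± 4.08 to 7.48 ± 1.61 FPKM (adjusted p = 0.0225), as 1 of 3 erythrocyte markers. The epithelial keratin gene krt18b fell by 0.54 on the log2 scale (adjusted p = 0.0378), as 1 of 5 intestine and bile duct markers. The krt18b call was lost without any 1 library, with no filter, after scaling without exocrine genes, with the replicate block and with the exocrine covariate, and that of hemgn without HDH replicate 1 or 2. Some intestine markers stood highest in PS replicate 1. fabp2, an intestinal fatty acid-binding protein gene, read 39.96 FPKM there, 0.634 and 0.761 in the other PS libraries and 4.52, 7.497 and 5.297 in HDH (adjusted p = 0.840). cdx1b and muc2.1, which lay under the filter, read 0.861 and 0.829 FPKM there and at most 0.0266 and 0.0629 in any other library. Adjusted over each list alone the counts were unchanged. None of 7 leukocyte markers passed by either adjustment (cd74a 166 ± 14.8 and 193 ± 22.3 FPKM, cd4-2.2 1.42 ± 0.331 and 0.796 ± 0.224). The same held for the 4 fibroblast and stellate cell markers. Among these acta2 stood at 1.46, 1.46 and 1.47 FPKM in HDH and at 4.57, 1.38 and 1.304 in PS and col1a2 at 1.32 ± 0.456 and 1.04 ± 0.196. Nor did plin1, the only measured adipocyte marker, pass (45.7 ± 0.713 and 46.1 ± 6.80 FPKM).

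Egg coat and cell division transcripts were seen mainly in PS replicate 1. zp3b, an egg coat glycoprotein gene, read 21.6, 2.32 and 0.593 FPKM in the 3 PS libraries and 0.193, 0 and 0.167 in HDH. The mitotic genes ccnb1 and plk1 read 13.3 and 4.91 FPKM in PS replicate 1, against at most 2.15 and 0.724 in any other library. None of the 4 cell cycle genes passed by either adjustment. In the list of 9 vitellogenin and egg coat genes 2 were lower in PS by both adjustments and none higher. The oestrogen receptor gene esr2b fell from 55.4 ± 1.33 to 25.7 ± 4.36 FPKM (adjusted p = 0.00898). vtg8, a yolk precursor gene, fell by 0.58 on the log2 scale (adjusted p = 0.0452), a call that ended under median-of-ratios scaling and without any 1 library except HDH replicate 2. The vitellogenin gene vtg3 varied within HDH, at 148, 0.921 and 88.2 FPKM, and stood at 29.8, 12.9 and 18.8 FPKM in PS.

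**Figure D4:**
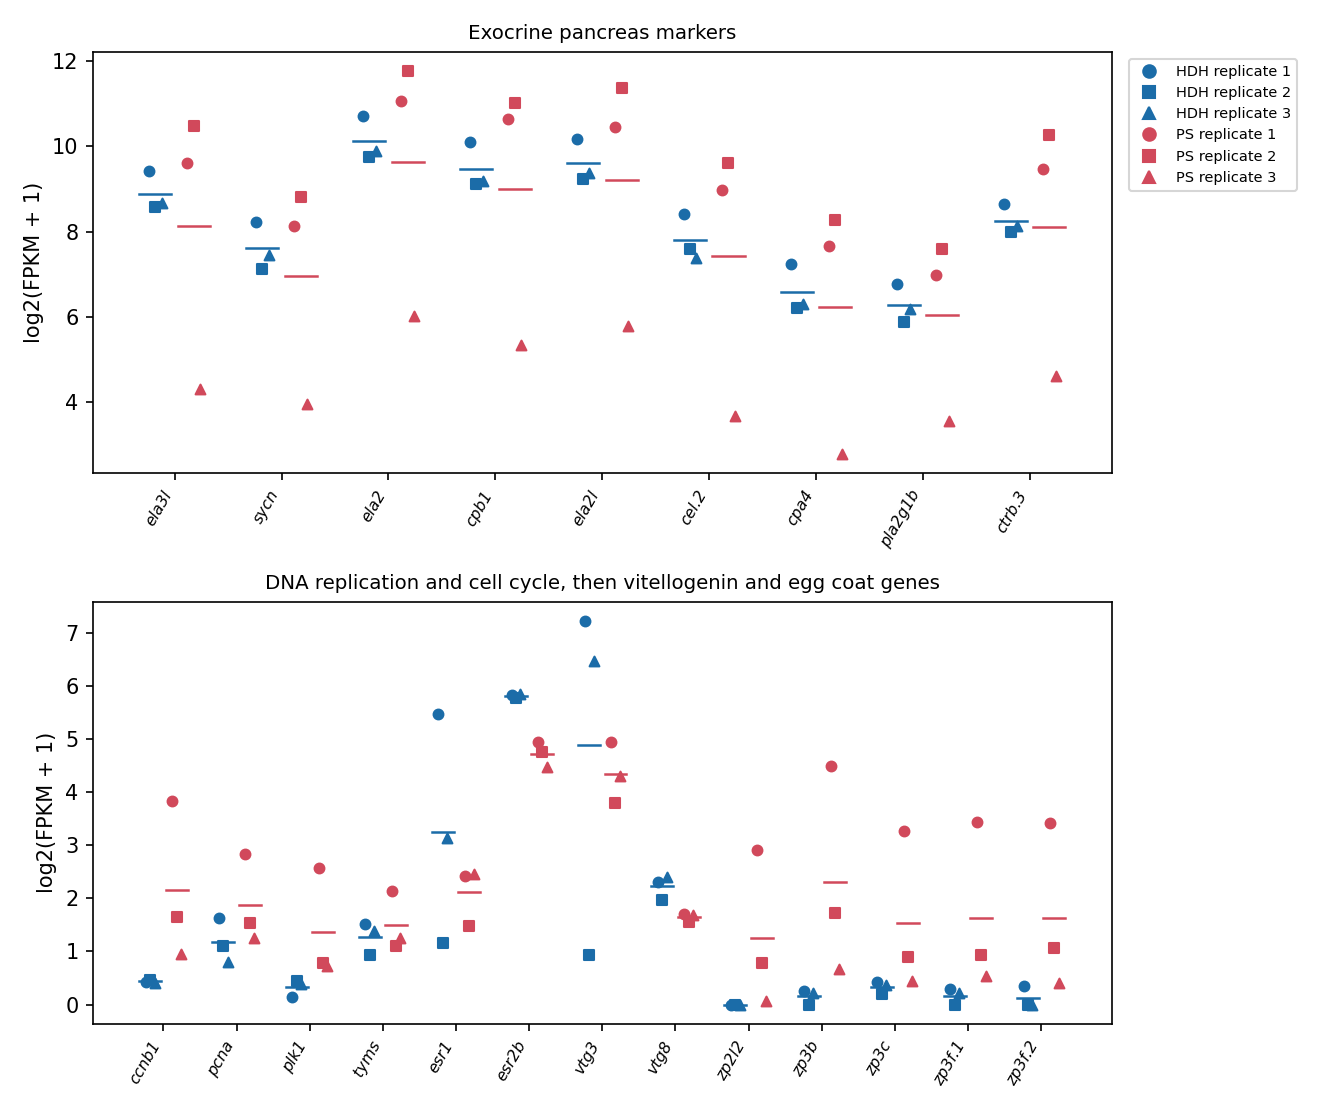
log2(FPKM + 1) of each library for the 9 exocrine pancreas markers (top) and for 4 cell cycle genes followed by 9 vitellogenin and egg coat genes (bottom); points are libraries, with colour for the breed and shape for the replicate number, and short lines are means of the 3 log2 values. PS replicate 3 lies lowest in all 9 exocrine genes, and PS replicate 1 highest in the 4 cell cycle genes and the 5 egg coat (zp) genes.

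Clock and stress genes were called in both directions. Of 9 circadian clock genes, the repressors nr1d2a and ciarta fell by 1.79 ± 0.37 and 1.36 ± 0.27 on the log2 scale and per3 rose by 0.93 ± 0.16 (SE, adjusted p = 0.0295, 0.0252 and 0.0178). All 3 calls were lost without HDH replicate 1 or 3, those of nr1d2a and ciarta without PS replicate 2, and that of nr1d2a without HDH replicate 2. With the replicate block nr1d2a and per3 lost their calls, and with no filter nr1d2a and ciarta. Adjusted over the list alone, 4 were lower and 1 higher. Of 8 heat shock and ER stress genes, pdia4, a protein disulfide isomerase gene, rose from 4.87 ± 1.35 to 16.5 ± 4.77 FPKM (adjusted p = 0.0131). In contrast herpud1 fell by 0.99 and calr by 0.61 on the log2 scale, with the same counts adjusted over the list alone. calr lost its call under median-of-ratios scaling and without any 1 library, and herpud1 without HDH replicate 2, HDH replicate 3 or PS replicate 2. Both also lost it with the replicate block. Among 7 proteasome genes psma2a fell by 0.46, by both adjustments, and lost its call in the same fits as calr. Of 7 genes of xenobiotic metabolism, nr1i2, the pregnane X receptor gene, and ugt5d1, a glucuronosyltransferase gene, fell by 0.61 and 0.74 and none rose (2 lower and 2 higher when adjusted over the list alone), both calls being lost without any 1 library. None of 7 interferon-stimulated genes passed over all genes, and 3 were lower when adjusted over the list alone. ifih1 had a log2 fold change of -0.80 ± 0.21 and mxe of -1.42 ± 0.39 (SE, adjusted p = 0.0560 and 0.0614). With a pseudocount of 0.1 both were called lower, at -1.14 and -2.71 (adjusted p = 0.0419 and 0.0337), as was mxe without HDH replicate 1 at -1.84 (adjusted p = 0.0205). Without HDH replicate 1 the list was lower in PS (camera adjusted p = 0.00723, p = 0.129 with an estimated correlation). With no filter on low values the interferon and proteasome lists were both called lower (camera adjusted p = 0.0493 each, p = 0.327 and p = 0.128 with an estimated correlation). Of the 23 lists with enough members for a set test, the cholesterol and hepatocyte lists were the 2 past the threshold with a preset correlation. With an estimated correlation 0 of the 23 passed. Other splits of the 6 libraries gave up to 11 lists with the preset correlation. The cholesterol list was also called in 4 and the hepatocyte list in 5 of the other 9 splits.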

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

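The fit with an exocrine pancreas covariate was chosen after seeing the data (870 higher, 1473 lower, 2 lists); the other alternatives were planned. Against 799 higher and 1437 lower genes, no fit except those named here moved a count by over 1.5 times. With a log2 fold change of at least 1, 384 were higher and 582 lower, since the threshold is stricter. With a mean of at least 5 FPKM, 427 were higher and 646 lower, as only 6370 genes were tested. Leaving out 1 library gave 307 to 718 higher and 532 to 986 lower genes, with fewer samples in each fit, and 2 to 3 lists. With the replicate block, 466 were higher and 762 lower. Same-numbered samples did not deviate together (correlations 0.102, -0.0284 and 0.0256), and 3 of 6 samples correlated best with their own number, so the labels' numbers are not taken to pair samples. Of the 2236 calls, 1812 were shared under median-of-ratios scaling, 1838 under quantile normalization and 1139 under the replicate block. Against 2 lists, no filter on low values gave 3 (cholesterol, interferon-stimulated and proteasome, all lower, with the hepatocyte list lost), quantile normalization gave 1, and an estimated correlation and fry gave 0 each, the former because the correlation is no longer preset; the other causes were not tested. In the test of fry for a change in either direction, 17 of 23 lists passed, among them the cholesterol, hepatocyte and bile acid synthesis lists (adjusted p = 0.0128, 0.00487 and 0.000119). That test makes no comparison with other genes. As 5436 of the 18159 genes tested had an unadjusted limma p under 0.05, a pass does not single out a list. Of 1134 values of 77 named genes over the alternatives, 896 kept their side of the threshold, 229 lost it, 9 gained it and 0 reversed; 15 of the 896 changed sign without a call in either fit, and 21 of the genes were not tested at a mean of at least 5 FPKM. A robust variance model cannot enter camera, and count tests were not run on FPKM. Depth limits genes near 1 FPKM, and absolute depth is unknown.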

Other observations

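The tests on oocyte markers and on other splits of the samples were written before their results were seen; the tests on hepatocyte share, scaling, clock genes, oestrogen response, neighbouring genes, unplaced sequences and symbol families were chosen after the patterns were seen.

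Some genes outside the lists were listed at 0 throughout 1 breed. At 0 in all 3 PS libraries and at 1 FPKM or more in all 3 HDH libraries were 27 genes, and 10 showed the opposite. The highest were an unnamed gene on chromosome 19 (24790146 to 24811242), with 152, 180.2 and 75.5 FPKM in HDH, and another on chromosome 21 (22499427 to 22500906), with 32.8, 45.8 and 45.1 FPKM, both listed at 0 in PS. The named ones were prr35, nrn1a (3.64, 4.73 and 2.86 FPKM in HDH) and s100a1, which was listed at 0 in HDH and at 32.9, 6.43 and 1.301 FPKM in PS. s100a1 did not pass the threshold (limma adjusted p = 0.0702) and was highest in PS replicate 1, the library with the highest oocyte markers. An unnamed called gene on chromosome 26 (17394737 to 17396590) fell likewise across the PS libraries, at 64.6, 9.82 and 3.22 FPKM (limma adjusted p = 0.0419). So did an unnamed gene on chromosome 8 (13524055 to 13525176), at 14.6, 2.91 and 1.34 FPKM, which was not called. The other genes listed at 0 in HDH showed no such fall. These genes were singled out after their values were seen. Called genes also lay side by side: of 16868 pairs of adjacent tested genes, 268 were called in the same direction, against 138 on average and at most 171 in 1000 shuffles of the calls (permutation p = 0.001, the smallest they can give). Runs of at least 4 such neighbours numbered 11, against at most 5 in a shuffle. Among them were a run on chromosome 21 (21499483 to 21691467) with ghrb, lower in PS, and a run on chromosome 6 (5130812 to 5234249) with acp5a, higher in PS. The longest run held 5 genes, against up to 6 in a shuffle. Some runs held adjacent loci outside the reference annotation, which the shuffles treat as separate genes. Whether these are parts of 1 transcript was not tested. A search over 59 families of genes whose symbols open with the same letters found none past the threshold (lowest adjusted p = 0.717, limma camera).

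For 48 called genes under 0.1 FPKM throughout 1 breed and at 1 FPKM or more throughout the other, reads could have been assigned to a neighbouring copy. Of the 47 with a flanking locus, 31 had none that gained as much as 10% of the FPKM lost (upper 95% limits). For these 31 that argues against reads moved to an adjacent locus only. Whether the flanking loci are copies was not tested and copies elsewhere were not covered, so reads moved to such copies stay open. For the other 16 a move to an adjacent locus cannot be told apart from a change in expression. A neighbour called in the opposite direction was seen for 3, against a mean of 3.42 in 1000 shuffles (permutation p = 0.691). Sequence that differs between the breeds and the reference, such as a copy lost or diverged in 1 breed, remains a candidate explanation. Of the 48 genes 35.4% lay on unplaced sequences, against 20.7% of the other called genes (Fisher's exact p = 0.0192, odds ratio 2.09, 95% interval 1.08 to 3.94). That cannot be told apart from regulated expression of such copies without reads, and a breed difference in regulation stays open and untested. For the called gene on chromosome 26 that was highest in PS replicate 1, RNA of ovary in that sample stays open too.

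Egg coat and cell cycle transcripts in PS replicate 1 may come from RNA of ovary in that sample. Of 22 oocyte markers outside the gene lists, 20 were highest in PS replicate 1, and their median log2 difference from the other libraries (1.61) lay at percentile 100 of 10000 matched random lists, whose median was 0.02. The most abundant, h1m, npm2b and ccna1, read 33.8, 29.5 and 15.9 FPKM there; 13 markers reached 1 FPKM, and at these PS replicate 2 stood at a median of 14.7%, PS replicate 3 at 4.54% and the HDH mean at 0.659% of the level in PS replicate 1, so lower amounts in the other PS libraries remain open. An oestrogen response of hepatocytes would put vitellogenin genes and esr1 highest in that library, and 0 of the 3 tested were, with esr1 at 4.38 FPKM against 43.4 in HDH replicate 1. Among the PS libraries, however, vtg3 and vtg8 were highest there (29.8 and 2.26 FPKM, against at most 18.8 and 2.23), so such a response stays open. The intestine markers fabp2, cdx1b and muc2.1 were highest in the same library, so RNA of organs other than ovary stays open too.

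A smaller share of hepatocytes in PS, with like marker expression per cell, would lower the hepatocyte markers along with the cholesterol synthesis genes. The mean of the markers was instead higher in PS by 0.31 ± 0.12 (SE of log2 values). That of the cholesterol list was at -0.83 ± 0.29. This argues against a smaller share as the whole cause only if marker expression per cell was alike in the breeds. The rise itself was not firm, as 12 of 15 markers did not pass. The list's call was lost with an estimated correlation (camera adjusted p = 0.948) and in fry (adjusted p = 0.216). Marker expression per cell and the share of hepatocytes cannot be told apart here, so the share was not measured. Scaling between libraries as the whole cause is argued against, as the cholesterol list's median log2 fold change was at most -0.82 under the 3 other scalings. A difference in time of day or feeding before sampling could act on sterol and clock genes alike, and 3 of 9 clock genes passed the threshold, with calls that were each lost without HDH replicate 1 or 3. As the labels give neither, time or feeding and breed cannot be told apart here, and a breed difference in sterol synthesis stays open and untested.

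The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The breeds gave 799 genes higher and 1437 lower, and the highest number in either direction in another split was 1, so that 1 of the 10 splits gave as many. Every other split mixes the breeds, so any breed difference adds to the spread within its groups and lowers its gene calls. Those counts therefore do not show how many calls would arise without a breed difference. For the lists, 8 of 10 splits gave 2 or more, and the highest other was 11, in the split that put HDH replicate 1 with PS replicates 1 and 3. The cholesterol list was called in 4, the hepatocyte list in 5 and the exocrine pancreas list in 7 of the other 9 splits, so a set test call alone does not single out the breeds.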
